A study of Mus musculus with 11 samples.

How the data were processed

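RNA from hepatocytes of 12-week-old male mice was measured on 11 expression arrays. The labels give 4 genotypes: wildtype (n = 2), deletion of Nemo in liver parenchymal cells (Nemo KO, n = 3), deletion of Cxcr6 (Cxcr6 KO, n = 3) and deletion of both (double KO, n = 3). Per the labels' protocols, 300 ng of total RNA per sample was amplified and labelled with a whole-transcript kit. Per the submitters' processing notes, the authors used Affymetrix Expression Console, RMA (robust multi-array average, which corrects background, normalizes quantiles and summarises probes) and Transcriptome Analysis Console, with no versions given. The genome build behind the row names is not given in the sources used here, so no coordinates are printed. The deposited values are log2 signals, 1 per transcript cluster and array, in a table of 65956 rows. Arrays carry no read depth, and the number of arrays limits the precision. Column medians lay between 5.19 and 5.38 on the log2 scale, and values ran from 1.79 to 19.93, with the most abundant transcripts near that ceiling, where differences are compressed.

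Gene names came from the platform annotation, in which 30604 rows have 1 gene symbol, 2146 have several and 33206 have none. Rows with several or no symbols were not named or tested. Symbols were updated through gene identifiers against the mouse RefSeq table of assembly GRCm38.p6: 22818 named rows matched and 827 symbols changed. For each of the 30142 genes with a named row, the row with the highest mean over the 11 arrays was used (355 genes had more than 1 row). A gene was tested if its highest group mean reached the median of the row means of the whole table, 5.27 on the log2 scale, which left 18337 genes. Trp53 had no row with a single symbol and Gpc3 fell below this level, so neither was tested. Rows of near-identical family members (Selenbp1 and Selenbp2, the Dsg1, Hsd3b, Mup, Serpina1, Saa and Lyz genes) can share signal, and a pseudogene row such as Mpc1-ps can carry signal of its parent gene.

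All 4 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust), with a mean per group and no other term. The fit had 7 residual degrees of freedom and a prior of 2.13. The 5 comparisons were Nemo KO against wildtype, double KO against Nemo KO, double KO against Cxcr6 KO, Cxcr6 KO against wildtype, and the interaction, which is the Nemo effect without Cxcr6 minus the Nemo effect with Cxcr6. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called changed at 5%. Errors of log2 fold changes are standard errors from this fit. Values of a group are means ± SD. The labels call the replicates biological and do not say in words that each is a separate mouse.

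The 44 gene lists (31 of pathways and programs, 13 of cell type markers) were fixed before the data were examined. Of 1135 listed gene entries, 841 were tested. Each list was tested with limma's camera with the inter-gene correlation preset at 0.01, adjusted over all 220 list tests. Members were counted after adjustment over all genes tested and again adjusted over the list alone. With an estimated correlation, none of the list calls held in any of the 5 comparisons. The self-contained test fry, which asks whether a list's genes move on balance in a single direction, was a further alternative, under which 3 calls held for double KO against Nemo KO, 7 for double KO against Cxcr6 KO, 1 for Nemo KO against wildtype, 0 for Cxcr6 KO against wildtype and 1 for the interaction. Agreement between comparisons that share no array was described by the share of called genes with the same sign and by correlations across genes, which are not independent replicates. The shares have exact Clopper-Pearson intervals at 95%. These intervals count each gene as independent, so they do not measure the spread between mice.

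Named genes followed a rule fixed at the same time: for each comparison the 8 highest and 8 lowest log2 fold changes among genes past 5%, leaving out predicted and unnamed models, microRNAs, small nucleolar RNAs and olfactory receptors, some of which had larger changes (in double KO against Nemo KO, Mir1948 by 4.97, Olfr1034 by 4.05 and F830016B08Rik by 3.79); up to 4 members with the smallest p of each list; and, in every comparison, Ikbkg, Cxcr6, Cxcl16, Cdkn1a, Trp53, Mki67, Afp and Gpc3. Genes named outside it are marked as chosen after their values were seen.

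The fits were tested on simulated values for the 18337 genes drawn from a mean and residual SD per gene, with 50 genes changed in a single group at each of 1.5-, 2-, 4- and 8-fold. The shares recovered at these folds were 38%, 78%, 96% and 96% for double KO against Nemo KO and 30%, 72%, 94% and 96% for double KO against Cxcr6 KO. They were 24%, 42%, 90% and 98% for Nemo KO against wildtype, 30%, 48%, 92% and 98% for Cxcr6 KO against wildtype, and 14%, 42%, 82% and 90% for the interaction, with 4 to 8 false calls and no wrong sign. For double KO against Nemo KO only, camera recovered 4 of 4 shifted lists among 20, with 0 false calls. The simulated genes were uncorrelated, so this does not test the preset correlation on the measured lists. The simulated groups also had equal variance, unlike the measured ones. The cell cycle list mean, for example, had an SD of 1.073 in wildtype, 0.102 in Nemo KO, 0.041 in Cxcr6 KO and 0.746 in double KO. The simulated recovery and false calls therefore do not test the comparisons with wildtype or the interaction at their measured spread. Alternatives covered the filter, the choice of row, normalization, the variance model, array weights, the arrays in the fit, the replicate number as a block, the threshold and each array left out in turn.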

Results

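Hepatocytes were profiled from mice in which Nemo, Cxcr6 or both had been deleted. Nemo (gene symbol Ikbkg) is the regulatory subunit of the IkB kinase complex that activates NF-kB, and mice lacking it in hepatocytes develop chronic liver injury and tumours. Cxcr6 is a chemokine receptor of NKT and T cells, and Cxcl16 is its ligand. The study concerned the part Cxcr6 plays in this liver disease. The source names place wildtype and Nemo KO in one mouse line (without and with Cre recombinase) and Cxcr6 KO and double KO in another, so the 2 Nemo comparisons lie within a line, while Cxcr6 status and line cannot be told apart.

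Neither targeted gene fell on the arrays. Ikbkg had a log2 signal of 9.24 ± 0.32 (SD, n = 2) in wildtype, 9.32 ± 0.13 (n = 3) in Nemo KO, 9.15 ± 0.03 (n = 3) in Cxcr6 KO and 9.05 ± 0.39 (n = 3) in double KO. Cxcr6 lay between 5.18 and 5.41 in all 4 groups, close to the array medians. Each row summarises a whole transcript, and whether its probes lie in the deleted part is not known, so these values do not check the genotype labels. The groups with and without Nemo deletion were separated by Ly6d, a membrane-anchored surface protein, whose log2 signal was between 11.37 and 15.60 in the 6 arrays of Nemo KO and double KO and between 4.80 and 5.58 in the other 5.

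The 2 wildtype arrays differed from each other more than replicates of other groups did. Their correlation across all rows was 0.984, against 0.990 to 0.995 for the other pairs of arrays of the same group. Wildtype replicate 2 had a Mki67 (a proliferation marker) log2 signal of 11.18, against 5.35 in replicate 1, and its male-biased liver genes had a mean of 13.72, against 15.37. Counts and the main list results of each comparison with wildtype are therefore also given without replicate 2. List calls changed without replicate 1 as well, so the lists without replicate 2 are not a corrected result. Single genes are given with both wildtype arrays in the fit. That fit gives each gene a single variance for all 4 groups. Where the wildtype arrays spread more than the other groups, errors and adjusted p against wildtype can be too small.

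**Figure D1:**
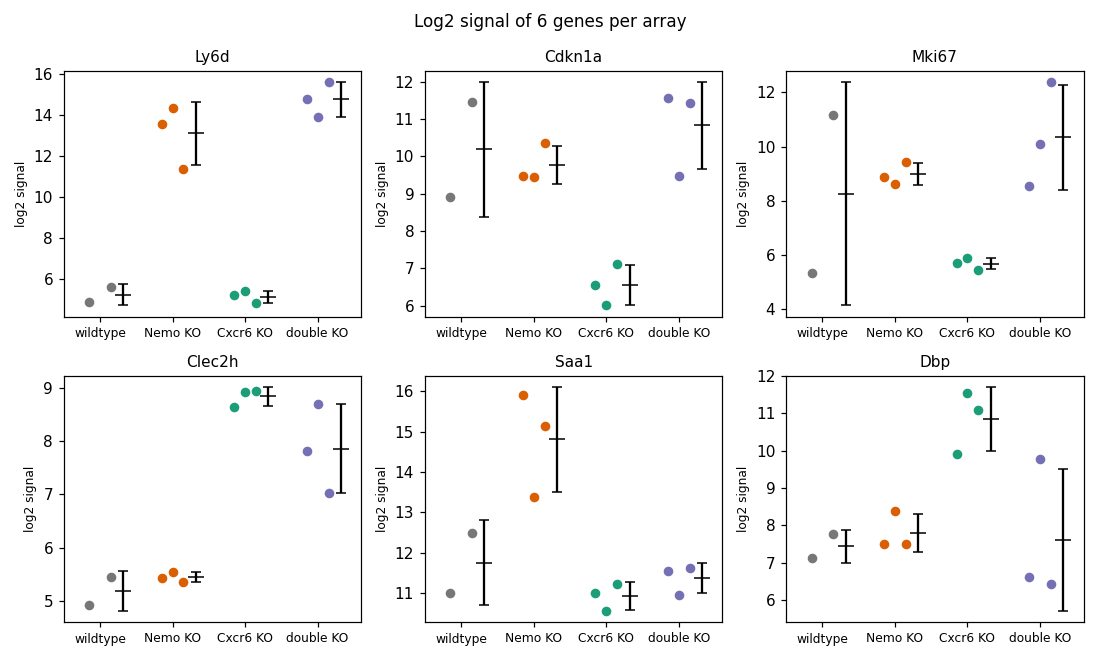
Log2 signal (vertical axis) of Ly6d, Cdkn1a, Mki67, Clec2h, Saa1 and Dbp in each of the 11 arrays, by genotype; points are arrays and bars are means ± SD. Ly6d lies at 11.37 or above in the 6 Nemo-deleted arrays and at 5.58 or below in the other 5, and Mki67 differs between the 2 wildtype arrays (5.35 and 11.18).

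The comparison of double KO with Nemo KO gave the effect of Cxcr6 loss, and of mouse line, in Nemo-deleted livers. The acute-phase gene Saa1 fell by 3.43 ± 0.60 on the log2 scale (10.8-fold, 14.81 ± 1.29 in Nemo KO, 11.38 ± 0.37 in double KO, adjusted p = 0.0487). The male-biased organic anion transporter Slco1a1 fell by 2.14 ± 0.31 (adjusted p = 0.0329), and Alas2, the first enzyme of haem synthesis in erythroid cells, fell by 1.54 ± 0.27 (adjusted p = 0.0487). The 20-alpha-hydroxysteroid dehydrogenase gene Akr1c18 rose by 2.31 ± 0.23 (4.95-fold, adjusted p = 0.00626), and the oncofetal RNA-binding protein gene Igf2bp3 rose by 0.76 ± 0.11 (adjusted p = 0.0291). Both lay near the array medians in Nemo KO (5.45 ± 0.15 and 5.42 ± 0.14), so the 4.95-fold is not an exact ratio of RNA amounts. In all, 109 of 18337 genes changed, 67 up and 42 down.

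Among genes the naming rule covers, the largest other rises were those of Clec2h (2.40 ± 0.35), Acpp, an acid phosphatase (2.02 ± 0.28), the selenium-binding proteins Selenbp2 (1.96 ± 0.21) and Selenbp1 (1.70 ± 0.20), the steroid dehydrogenase Hsd3b3 (1.96 ± 0.21), the lipid kinase Pik3c2a (1.90 ± 0.22) and the carbonyl reductase Cbr1 (1.72 ± 0.21). Falls also included Lnx1, Prelid2, Cdcp1 and the transporter genes Slc22a28 and Slc22a30, with log2 fold changes between -1.77 and -0.74. The cell cycle inhibitor Cdkn1a (1.06 ± 0.72, adjusted p = 0.474) and Mki67 (1.36 ± 1.35, adjusted p = 0.624) did not pass, nor did the fetal liver gene Afp (0.29 ± 0.16, adjusted p = 0.377).

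By the camera test, 15 of the 44 lists differed between double KO and Nemo KO. Of these, liver tumour markers, cell death genes and cholangiocyte and progenitor markers also passed fry (adjusted p = 0.0177, 0.0333 and 0.0333). Genes of cell death, p53 targets, fibrosis, female-biased genes and the urea cycle were higher (medians 0.261, 0.206, 0.219, 0.755 and 0.226). Their camera adjusted p was 0.00845, 0.00874, 0.00259, 0.0131 and 0.0297, and 0.44 to 0.709 with an estimated correlation. No member of these passed over all genes. Liver tumour markers were higher (median log2 fold change 0.64, 17 of 19 higher, camera adjusted p = 1.73e-05, adjusted p = 0.44 with an estimated correlation). Akr1c18, Igf2bp3 and the tetraspanin Tspan8 (1.02 ± 0.17) passed over all genes, and 7 members rose when adjusted over the list alone. Acute-phase genes were lower (median -0.33, 25 of 27 lower, adjusted p = 3.9e-07, adjusted p = 0.475 with an estimated correlation), with Saa1 past 5% over all genes and 3 members lower adjusted over the list alone. Male-biased liver genes were lower (median -0.57, 18 of 22, adjusted p = 2.55e-05, adjusted p = 0.628 with an estimated correlation). Slco1a1 and the antitrypsin gene Serpina1e (-0.64 ± 0.11) fell and Selenbp2 rose over all genes; 4 members were lower and 1 higher adjusted over the list alone. Nrf2 targets and genes of fatty acid oxidation were higher (medians 0.52 and 0.38, adjusted p = 0.000141 and 0.000228). No member of either passed over all genes; 4 and 9 members rose adjusted over the list alone, and the calls had adjusted p = 0.602 and 0.664 with an estimated correlation. Cell cycle genes were higher in 35 of 37 (median 0.56, 0 past 5% either way, adjusted p = 0.00167, adjusted p = 0.769 with an estimated correlation). Their means were 6.435, 7.052 and 7.921 in double KO replicates 1 to 3 and 6.491, 6.426 and 6.626 in Nemo KO. Double KO replicate 1 thus lay among the Nemo KO arrays. Of the 15 list calls, 12 held without double KO replicate 3 and 12 held without Nemo KO replicate 1.

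Markers of other cell types moved with these lists. Endothelial markers were higher in double KO than in Nemo KO (median 0.78, 23 of 24, adjusted p = 2.94e-13, adjusted p = 0.475 with an estimated correlation). The angiopoietin receptor gene Tek (1.10 ± 0.18) passed over all genes and 20 markers rose adjusted over the list alone. Markers of stellate cells and fibroblasts and of Kupffer cells and macrophages were also higher (medians 0.44 and 0.55, adjusted p = 0.000154 and 0.0218, and 0.608 and 0.77 with an estimated correlation). None of these passed over all genes, and 4 and 0 rose adjusted over the list alone. The macrophage means of the 2 groups overlapped (7.95 in double KO replicate 1, 8.486 in Nemo KO replicate 3). Cholangiocyte and progenitor markers were higher in 10 of 14 (median 0.61, camera adjusted p = 0.00221, adjusted p = 0.475 with an estimated correlation). Of these, Tspan8, which also stands in the tumour marker list, passed over all genes, and 6 rose adjusted over the list alone. Without Nemo KO replicate 1 the count of changed genes was 19, and with only these 2 groups in the fit it was 11. The split of 67 up and 42 down became 174 and 27 with each array centred on its median, which moved the median of all genes from 0.04 to 0.16, and 66 and 22 with quantile normalization.

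The comparison of double KO with Cxcr6 KO gave the effect of Nemo deletion in mice without Cxcr6. Ly6d rose by 9.65 ± 0.70 on the log2 scale (803-fold, 5.12 ± 0.29 to 14.77 ± 0.85, adjusted p = 0.00188) and the nodal adhesion protein gene Gldn by 5.64 ± 0.50 (adjusted p = 0.00377). In Cxcr6 KO both lay near the array medians (Ly6d 4.80 to 5.37, Gldn 4.92 to 5.56). The 803-fold is thus a ratio of signals and not an exact ratio of RNA amounts. Cdkn1a rose by 4.28 ± 0.72 (19.4-fold, 6.55 ± 0.55 to 10.83 ± 1.17, adjusted p = 0.0163), and the Cxcr6 ligand gene Cxcl16 rose by 0.78 ± 0.17 (adjusted p = 0.03). Cdkn1a had means of 10.19 ± 1.81 in wildtype and 9.77 ± 0.52 in Nemo KO. Double KO thus lay nearer to these groups than Cxcr6 KO did. The male-biased steroid dehydrogenase Hsd3b5 (-6.06 ± 1.42, adjusted p = 0.038) and the G-protein regulator Rgs16 (-4.75 ± 1.02, adjusted p = 0.0303) fell. Rgs16 had a mean of 15.29 in Cxcr6 KO, 12.35 in wildtype, 9.17 in Nemo KO and 10.54 in double KO. Dbp and Usp2, named below, were also highest in Cxcr6 KO. In all, 1358 genes changed, 631 up and 727 down. Of the 47 genes called in Cxcr6 KO against wildtype, 17 that rose there fell here and 9 that fell there rose here. Independent lists would give 1.27 and 0.52, but both comparisons use the Cxcr6 KO arrays, which favours opposite signs. For these genes double KO moved back in the direction of wildtype. A further 2 rose in both.

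Other large rises were those of Ifi27l2b (5.64 ± 0.98), the retinol dehydrogenase Dhrs9 (4.98 ± 0.86), choline kinase Chka (4.33 ± 1.08), the Myb-family gene Mybl1 (4.29 ± 0.72) and Pdk4, which restrains pyruvate oxidation (3.95 ± 1.00). Other large falls were those of the clock output factor Dbp (-3.25 ± 0.83), Slco1a1 (-2.53 ± 0.31), the succinate receptor Sucnr1 (-2.40 ± 0.46), the acyl-CoA thioesterase Acot3 (-2.28 ± 0.33), the deubiquitinase Usp2 (-2.25 ± 0.54) and the growth factor signalling inhibitor Spry4 (-2.23 ± 0.33). Mki67 was 4.65 ± 1.35 higher with adjusted p = 0.0648 and Afp 0.46 ± 0.16 higher with adjusted p = 0.0951, so neither passed.

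**Figure D2:**
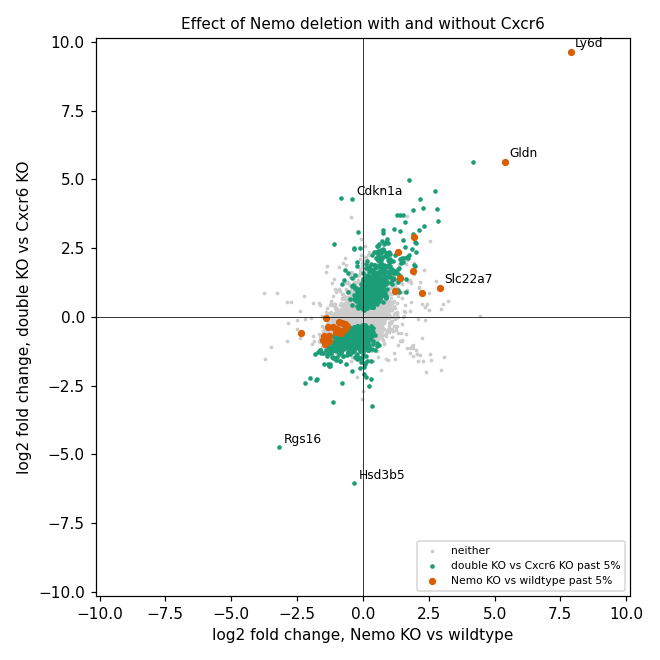
Log2 fold change of each of the 18337 genes tested for Nemo KO against wildtype (horizontal axis) and double KO against Cxcr6 KO (vertical axis). Green points passed 5% in double KO against Cxcr6 KO (1358 genes, unless also orange) and orange points in Nemo KO against wildtype (29 genes); Ly6d and Gldn lie far to the upper right, and Hsd3b5 and Rgs16 at the bottom.

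By the camera test, 19 lists differed in this comparison. Of 20 p53 targets, 7 rose and 1 fell over all genes (median 0.46, adjusted p = 1.46e-06, adjusted p = 0.44 with an estimated correlation, 11 up and 1 down adjusted over the list alone). Those that rose included Cdkn1a, the death receptor gene Eda2r (2.83-fold), the p53 ubiquitin ligase Mdm2 (0.61 ± 0.09) and the TRAIL receptor Tnfrsf10b (1.62 ± 0.25), while the stress sensor Sesn2 fell (-0.44 ± 0.11). Of 18 genes of senescence and its secretory phenotype, 5 rose and none fell (6 up adjusted over the list alone, median 0.26, adjusted p = 5.5e-05, adjusted p = 0.475 with an estimated correlation), among them the insulin-like growth factor binding protein Igfbp7 (3.87 ± 0.54) and the cytokine Il1a (1.62 ± 0.36). Of 21 cell death genes, 5 rose, including Casp1 (1.13 ± 0.19) and Fas (0.68 ± 0.13), and Bid fell (-0.62 ± 0.14, 7 up and 1 down adjusted over the list alone, adjusted p = 0.00267, adjusted p = 0.44 with an estimated correlation). Fas had means of 10.83 in wildtype, 10.79 in Nemo KO, 10.25 in Cxcr6 KO and 10.93 in double KO. Bid had 6.36, 6.12, 7.40 and 6.78 in the same order, so Cxcr6 KO lay apart for both. Tnfrsf10b had 5.43, 6.01, 5.17 and 6.79 and was highest in double KO. Of 37 cell cycle genes, the cytokinesis factor Ect2 (3.07 ± 0.77) rose over all genes while 19 rose and 1 fell adjusted over the list alone (median 1.03, adjusted p = 1.99e-09, adjusted p = 0.664 with an estimated correlation).

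Of 19 liver tumour markers, 11 rose and none fell over all genes, and 14 rose adjusted over the list alone (median 1.22, adjusted p = 1.11e-13, adjusted p = 0.238 with an estimated correlation). They included Ly6d, Tspan8 (1.65 ± 0.17), the Golgi membrane protein Golm1 (1.77 ± 0.19) and Igf2bp3 (0.97 ± 0.11). Of 23 genes of fibrosis and extracellular matrix, 11 rose over all genes and 18 adjusted over the list alone (median 0.49, adjusted p = 2.94e-13, adjusted p = 0.44 with an estimated correlation). Their leading members were the proteoglycans Dcn (3.70 ± 0.42) and Bgn (3.19 ± 0.43), the matricellular protein Sparc (1.93 ± 0.32) and galectin-1, Lgals1 (1.81 ± 0.19).

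Markers of endothelial cells, macrophages and stellate cells rose in the same comparison. Of 24 endothelial markers, 20 rose over all genes (23 adjusted over the list alone, median 1.39, adjusted p = 1.28e-22, adjusted p = 0.44 with an estimated correlation), with Ptprb (2.74 ± 0.34), Lyve1 (1.46 ± 0.12) and Pecam1 (1.33 ± 0.16) among them. Of 26 markers of Kupffer cells and macrophages, 10 rose (19 adjusted over the list alone, median 1.52, adjusted p = 3.14e-12, adjusted p = 0.475 with an estimated correlation), including Lyz2 (2.69 ± 0.45) and the mannose receptor Mrc1 (2.38 ± 0.42). Of 15 stellate cell and fibroblast markers, 10 rose (13 adjusted over the list alone, median 0.78, adjusted p = 1.5e-12, adjusted p = 0.44 with an estimated correlation), including Rgs5 (2.26 ± 0.28). The lists of T cells, NK and NKT cells and neutrophils did not differ (adjusted p = 0.895, 0.992 and 0.992), with group means of 5.35 to 6.32, near the array medians. Fibrosis genes, several senescence genes and some tumour markers are also expressed by these other cells, and Dcn stands in both the fibrosis and the stellate list.

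**Figure D3:**
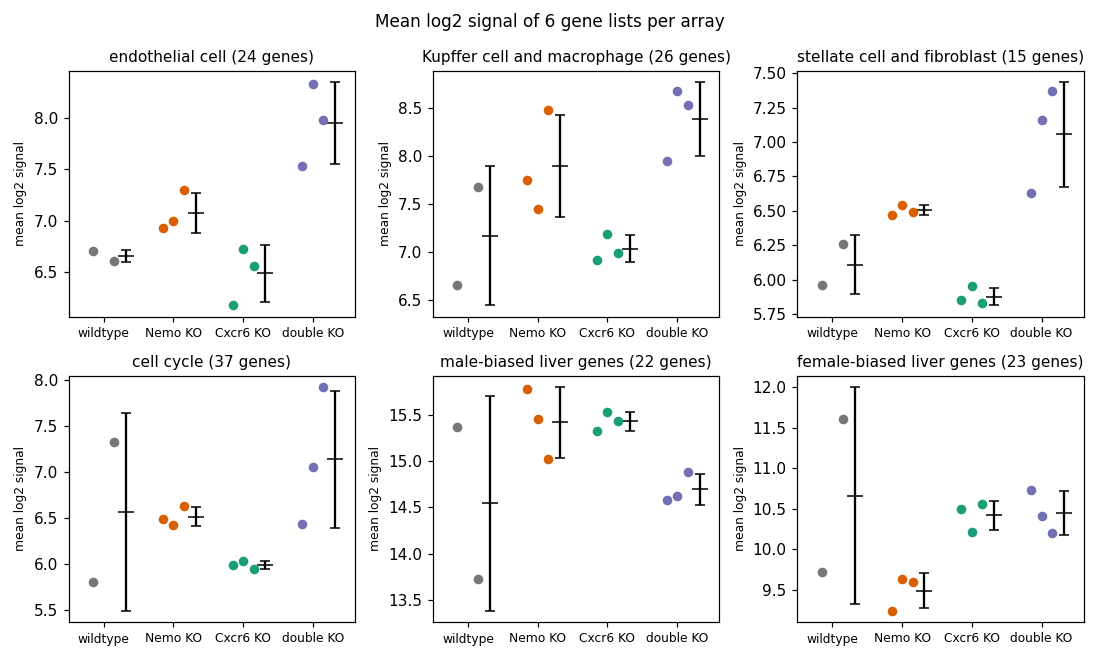
Mean log2 signal (vertical axis) of endothelial, Kupffer cell and macrophage, stellate cell, cell cycle, male-biased and female-biased gene lists in each of the 11 arrays, by genotype; points are arrays and bars are means ± SD. Endothelial markers average 7.95 in double KO and 6.48 in Cxcr6 KO, and wildtype replicate 2 lies apart from replicate 1 in cell cycle genes (7.33 and 5.81) and in both sex-biased lists.

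Fatty acid oxidation was the only metabolic list called lower in double KO against Cxcr6 KO. Of 25 genes of fatty acid oxidation and Ppara targets, Ppara itself (-1.28 ± 0.16), Acot3, Acot4 (-1.16 ± 0.18) and Acaa1b (-1.20 ± 0.26) fell and Pdk4 rose over all genes; 6 fell and 1 rose adjusted over the list alone (median -0.46, adjusted p = 0.00892, adjusted p = 0.7 with an estimated correlation). The fatty acid binding protein Fabp1 (-1.39 ± 0.23), the triglyceride enzyme Dgat2 (-1.42 ± 0.22) and the hepatocyte transcription factor Cebpa (-1.57 ± 0.39) fell, while the lists of hepatocyte markers and lipogenesis did not differ (adjusted p = 0.974 and 0.361). Of 22 male-biased liver genes, 5 fell over all genes and 8 adjusted over the list alone, where 2 rose, and the list did not pass (adjusted p = 0.211). The apolipoprotein Apoa4 rose by 3.49 ± 0.44 and the acute-phase genes Itih3 (1.00 ± 0.15) and Orm2 (1.49 ± 0.28) rose, while Saa3 fell (-0.82 ± 0.17). Of the 27 acute-phase genes, 4 rose and 1 fell (7 and 2 adjusted over the list alone, median 0.45, adjusted p = 1.18e-05, adjusted p = 0.485 with an estimated correlation).

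Further lists were higher in this comparison. Of 24 growth factor, Notch, Wnt and Yap target genes, 4 rose, led by Hgf (2.38 ± 0.34) and Btc (1.29 ± 0.26), and 8 rose adjusted over the list alone (adjusted p = 1.39e-06, adjusted p = 0.475 with an estimated correlation). Of 26 complement and coagulation genes, C9 (0.94 ± 0.14), Hc (0.55 ± 0.11) and Cfi (0.45 ± 0.10) rose, and 4 rose adjusted over the list alone (adjusted p = 1.31e-06, adjusted p = 0.475 with an estimated correlation). Of 14 cholangiocyte and progenitor markers, 5 rose (5 adjusted over the list alone), including Pkhd1 (1.33 ± 0.20) and Cd24a (1.61 ± 0.31, list adjusted p = 0.000157, adjusted p = 0.44 with an estimated correlation). Lists of monocyte markers, interferon response, antigen presentation, Nrf2 targets and endoplasmic reticulum stress were also higher (adjusted p = 0.00224, 0.00269, 0.00577, 0.00722 and 0.0297, and 0.475, 0.7, 0.7, 0.665 and 0.7 with an estimated correlation). The mean of the Nrf2 targets was 11.946 in Cxcr6 KO and 12.395 in double KO, but not every member rose. Me1 had means of 16.25 ± 0.26 and 14.57 ± 0.48 in these groups, and Gstp1 17.41 ± 0.11 and 16.39 ± 0.38. The 26 NF-kB targets and 21 pathway components did not differ as lists (adjusted p = 0.204 and 0.773), and Saa3 was the only NF-kB target past 5%. The number of changed genes ran from 116 without Cxcr6 KO replicate 3 to 2342 without wildtype replicate 2, and was 201 and 205 without Cxcr6 KO replicate 2 and double KO replicate 3. The split of 631 up and 727 down became 657 and 462 with each array centred on its median, and 651 and 1099 with quantile normalization.

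The comparison of Nemo KO with wildtype gave the effect of Nemo deletion in mice with intact Cxcr6. Ly6d rose by 7.89 ± 0.78 on the log2 scale (237-fold, 5.21 ± 0.52 to 13.10 ± 1.55, adjusted p = 0.0246) and Gldn by 5.39 ± 0.55 (adjusted p = 0.0246). In wildtype both lay near or below the array medians (Ly6d 4.84 and 5.58, Gldn 4.55 and 4.83), so the 237-fold is not an exact ratio of RNA amounts. The organic anion transporter Slc22a7 (2.91 ± 0.35), the salt-inducible kinase Sik1 (2.26 ± 0.32), Slc35f2 (1.92 ± 0.27), the immune checkpoint ligand Vtcn1 (1.41 ± 0.18) and the terminal complement component C9 (1.22 ± 0.16) rose as well. The desmosomal cadherins Dsg1c (-2.34 ± 0.26), Dsg1a (-1.33 ± 0.16) and Dsg1b (-1.13 ± 0.15) fell, as did Acss3, Car8, Ybx3 and Nudt19, with log2 fold changes of -1.46 to -1.29. In all, 29 genes passed, 9 up and 20 down, while 4506 had an unadjusted p under 0.05. Cdkn1a (-0.42 ± 0.81, adjusted p = 0.797), Mki67 (0.72 ± 1.51, adjusted p = 0.815) and Cxcl16 (0.38 ± 0.19, adjusted p = 0.248) did not pass. Wildtype replicates 1 and 2 lay at 8.91 and 11.46 for Cdkn1a and at 5.35 and 11.18 for Mki67. The Nemo KO means of 9.77 ± 0.52 and 8.98 ± 0.42 lay above replicate 1 and below replicate 2, so both differences depend on the wildtype array.

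By camera, 19 lists differed between Nemo KO and wildtype, with few members past 5% over all genes. Genes of fibrosis and extracellular matrix were higher (median 0.26, 23 of 23, adjusted p = 6.73e-07, adjusted p = 0.475 with an estimated correlation, 0 past 5% over all genes and 1 adjusted over the list alone). Complement and coagulation genes were higher (median 0.26, adjusted p = 1.31e-06, adjusted p = 0.475 with an estimated correlation), with C9 past 5% over all genes and 7 members adjusted over the list alone. Kupffer cell and macrophage markers (median 0.68, 24 of 26) and endothelial markers (median 0.30, 24 of 24) were higher, with adjusted p = 2.62e-06 and 6.75e-06, and 0.664 and 0.665 with an estimated correlation. No marker of either passed over all genes or adjusted over the list alone. Male-biased liver genes were higher (median 0.61, 21 of 22, adjusted p = 9.64e-07, adjusted p = 0.557 with an estimated correlation) and female-biased genes lower (median -0.85, 19 of 23, adjusted p = 0.00728, adjusted p = 0.665 with an estimated correlation). Without wildtype replicate 2, 13 of the 19 list calls held, 6 were lost and 11 further lists were called. Both sex-biased calls were among those lost (male-biased median 0.05, adjusted p = 0.133, and female-biased median 0.28, adjusted p = 0.696), while the macrophage median was 1.07 with 5 markers past 5% over all genes. The medians of cholesterol synthesis (0.70 with both arrays) and lipogenesis (0.18) were then 1.44 and 0.68, with 8 and 6 members past 5% over all genes. Cell cycle genes (-0.02 with both arrays) were then called higher (0.66, adjusted p = 4.2e-06) and fatty acid oxidation genes (-0.63) lower (-0.997, adjusted p = 0.000821).

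Without wildtype replicate 2 the count of changed genes was 2380 (360 up and 2020 down), without wildtype replicate 1 it was 186, and without Nemo KO replicate 3 it was 1022. It was 0 with the replicate number as a block, with array weights, with only these 2 groups in the fit, or without Cxcr6 KO replicate 2 or 3. With each array centred on its median 89 genes rose and 1230 fell.

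The genes called under Nemo deletion mostly moved the same way in both Cxcr6 states. All 29 genes called in Nemo KO against wildtype had the same sign in double KO against Cxcr6 KO (exact interval 88.1% to 100%), and 7 passed upward and 11 downward in both, against 0.31 and 0.79 in independent lists. The 2 comparisons use the same variance estimate of each gene, so their calls are not independent and these numbers are only a reference. Of the 1358 genes called in double KO against Cxcr6 KO, 85.9% (83.9% to 87.7%) had the same sign in Nemo KO against wildtype. Both intervals count genes as independent and do not give the spread between mice. Across the 18337 genes the log2 fold changes correlated with Pearson r = 0.509 and Spearman rho = 0.455, and r was 0.221 without wildtype replicate 1. Without that array, 47.3% of the genes then called in Nemo KO against wildtype and 71.2% of those called in double KO against Cxcr6 KO had the same sign in the other comparison. Without wildtype replicate 2 these shares were 85.2% and 89.0%.

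The interaction tested whether the Nemo effect differed between Cxcr6 states, which cannot be told apart from mouse line. No single gene passed in limma (smallest adjusted p = 0.251), while 2155 genes had an unadjusted p under 0.05, and 88 and 232 genes passed without wildtype replicate 2 and 1. By camera, 15 lists differed. Endothelial markers (median log2 interaction 1.04, 18 members adjusted over the list alone) and liver tumour markers (median 0.83, 5 members) were raised more by Nemo deletion in mice without Cxcr6, with adjusted p = 1.6e-12 and 1.31e-06, and adjusted p = 0.475 and 0.44 with an estimated correlation. Male-biased liver genes were lower in all 22 members (median -1.27, 6 adjusted over the list alone, adjusted p = 1.66e-09, adjusted p = 0.475 with an estimated correlation). Cholesterol synthesis genes were lower too, in 16 of 17 (median -1.16, 0 adjusted over the list alone, adjusted p = 1.12e-05, adjusted p = 0.664 with an estimated correlation). Without wildtype replicate 2 the male-biased median was -0.64 and the cholesterol median -1.97, while the endothelial and tumour marker medians were 1.06 and 0.83. Of the 15 calls, 7 held without that array and 8 were lost. A further 3 lists were then called: lipogenesis (median -0.53, 3 members down over all genes, adjusted p = 1.2e-06), endoplasmic reticulum stress (0.77, 2 members up, adjusted p = 0.000487) and complement and coagulation (-0.09, adjusted p = 0.0469).

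The comparison of Cxcr6 KO with wildtype gave the effect of Cxcr6 loss, and of mouse line, with intact Nemo. Clec2h rose by 3.64 ± 0.39 on the log2 scale (12.5-fold, 5.19 ± 0.37 to 8.84 ± 0.17, adjusted p = 0.00925), Acpp by 3.40 ± 0.31 (adjusted p = 0.0046), the transporter Slc46a3 by 2.58 ± 0.36 (adjusted p = 0.0328) and Sugct by 2.40 ± 0.19 (adjusted p = 0.00261). Clec2h and Acpp (5.26 ± 0.21) lay near the array medians in wildtype, so the 12.5-fold is not an exact ratio of RNA amounts. Hsd3b3, Selenbp2, the peroxisomal thiolase Acaa1b and Ttc39c rose by 1.88 to 2.22. Prelid2 fell by 3.55 ± 0.30 (9.66 ± 0.81 to 6.11 ± 0.11, adjusted p = 0.00261), the ion channel gene Asic5 by 3.07 ± 0.43 and the ubiquitin ligase gene Nedd4l by 1.99 ± 0.31. The wildtype SD of Prelid2 exceeded that in Cxcr6 KO, while its fitted error rests on a variance common to all groups. Stap1, Cdcp1, Slc17a1, the interferon signalling factor Stat2 (-1.16 ± 0.13) and the splicing factor Tra2a fell by between 1.31 and 1.06. In all, 47 genes passed, 32 up and 15 down. Cdkn1a (-3.63 ± 0.81, adjusted p = 0.137) did not pass. Its Cxcr6 KO mean of 6.55 ± 0.55 lay below wildtype replicates 1 and 2 (8.91 and 11.46), which differ in how far.

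By camera, 15 lists differed between Cxcr6 KO and wildtype. Acute-phase genes were lower (median -0.38, 23 of 27, 7 adjusted over the list alone, adjusted p = 7.73e-08, adjusted p = 0.475 with an estimated correlation). Genes of cholesterol synthesis were higher in 17 of 17 (median 0.95, 0 adjusted over the list alone, adjusted p = 2.5e-06, adjusted p = 0.628 with an estimated correlation). Genes of fatty acid oxidation were higher (median 0.75, Acaa1b past 5% over all genes, 7 adjusted over the list alone, adjusted p = 6.57e-07, adjusted p = 0.528 with an estimated correlation). Endothelial and Kupffer cell markers were not called (adjusted p = 0.072 and 0.282), but Kupffer cell markers were called higher without wildtype replicate 2 (median 0.32, adjusted p = 0.0314). The counts were 361 without wildtype replicate 2, 493 without wildtype replicate 1, 8 and 9 without Cxcr6 KO replicate 2 and 3, 24 with a replicate block and 0 with only these 2 groups in the fit. Without wildtype replicate 2, the fatty acid oxidation call was lost (median 0.04, adjusted p = 0.0653), the acute-phase median was -0.25 and the cholesterol synthesis median was 1.81 with 5 members past 5% over all genes. The median of cell cycle genes, -0.49 with both arrays, was then 0.16. Of the 15 list calls 8 held without that array, 2 (cell cycle and antigen presentation) were called in the opposite direction, 5 were lost and 3 were added.

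The 2 Cxcr6 comparisons shared a small set of genes. Of the 47 genes called in Cxcr6 KO against wildtype, 91.5% (79.6% to 97.6%) had the same sign in double KO against Nemo KO, and 21 passed in both with the same sign, 17 up and 4 down, against 0.12 and 0.03 in independent lists. The variance estimate of each gene is again shared, so these calls are not independent either. They included Clec2h, Acpp, Hsd3b3, Selenbp1, Selenbp2, Sugct, Prelid2 and Cdcp1. Of the 109 genes called in double KO against Nemo KO, 68.8% (59.2% to 77.3%) had the same sign in Cxcr6 KO against wildtype. Across all genes the log2 fold changes of the 2 comparisons correlated little (Pearson r = 0.131, Spearman rho = 0.107). Without wildtype replicate 1 or 2, the share of same signs among genes called in Cxcr6 KO against wildtype was 46.9% and 51.5%.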

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

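The test of chromosome 9 and the splits of the arrays were planned before the data were seen, and the neighbour test was written when the shared gene names were known and before neighbours were counted. The tests on wildtype replicate 2 and on cell type markers were chosen only after the results were seen, and the limits of the Nemo test, of the test on non-parenchymal cells in that array and of the marker comparison were changed after a first value.

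The interaction test marked 15 gene lists as moving differently under Nemo deletion in the 2 Cxcr6 states, each by camera and none with an estimated correlation (adjusted p of 0.44 or more). Median log2 interactions were above 0 for endothelial markers (1.04), cell cycle (0.97), liver tumour markers (0.83), female-biased genes (0.74), cholangiocyte markers (0.74), Kupffer cell markers (0.60), stellate cell markers (0.60), growth factors (0.51), interferon response (0.43), p53 targets (0.30), cell death (0.27) and fibrosis (0.24). They were below 0 for male-biased genes (-1.27), cholesterol synthesis (-1.16) and pericentral genes (-0.46). Without wildtype replicate 2, 8 calls were lost: interferon (median 0.04, adjusted p = 0.73), Kupffer cell (0.09, 0.947), female-biased (0.21, 0.655), cell cycle (0.42, 0.543), cell death (0.20, 0.335), fibrosis (0.28, 0.0951), growth factors (0.36, 0.095) and p53 targets (0.33, 0.0629). The male-biased median was then -0.64 and the cholesterol median -1.97.

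Wildtype replicate 2 stood apart from wildtype replicate 1, with cell cycle genes higher by 1.52 on average, Cdkn1a at 11.46 against 8.91, and the female-biased cytochrome Cyp2b9 (chosen after its values were seen) at 16.49 against 7.63. At 42 genes that separate the 6 Nemo-deleted arrays from the other 4, it lay above the midpoint at 52.4%, where Nemo-deleted arrays left out in turn reached 87.7% to 97.8%, Cxcr6 KO arrays 0% and wildtype replicate 1 9.3%, so it lay between the classes, but its Ly6d level of 5.58, against 11.37 or more in every Nemo-deleted array, argues against a Nemo-deleted sample. A female mouse is argued against, since its Xist level of 5.77 lay within the 5.58 to 5.99 of the other 10 arrays of male mice. More non-parenchymal cells are argued against as the source of the whole difference, since they cannot raise the hepatocyte gene Cyp2b9 by 8.87 (other arrays 7.63 to 11.94) and the cell cycle mean of 7.33 exceeded the 6.49 and 6.63 of Nemo KO arrays with macrophage means as high, but some added macrophages stay possible (macrophage markers 1.02 higher, stellate cell markers 0.30 higher, endothelial markers -0.09). A difference between mice in proliferation, hormone state or illness stays open, since the design gives no label that would test it, and with 2 wildtype arrays neither can be called the typical one.

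Endothelial, macrophage and stellate cell markers were higher in double KO than in Cxcr6 KO isolates. A single odd array is argued against: without any 1 of the 6 arrays the endothelial median stayed at 1.26 or more, against 1.39. A lower share of hepatocytes in the Nemo-deleted isolates could raise all such markers alike, and it stays open, as does a change of these cells with genotype in the liver itself, which was not tested. Among markers with a mean of at least 7, endothelial genes rose by a median of 2.42 (10 genes) and macrophage genes by 1.78 (18 genes), a gap of 0.64 (adjusted permutation p = 0.0072) that is inside the SD of 0.67 of the macrophage genes, and lymphocyte lists lie near the array medians. The permutation moved markers between cell types, so it counts markers of the same 6 isolates as independent. The SD describes single genes, not the error of a median. The mean of at least 7 was taken over all arrays, double KO included, which favours markers high there. The 4 cholangiocyte markers rose by a median of 0.50, a gap of 1.92 that is beyond their SD of 0.81 (adjusted permutation p = 0.0072), and they are left out only by a minimum of 5 markers per type that was raised from 3 after the result was seen, so a lower hepatocyte share is open by that choice.

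The 21 genes changed alike in both Cxcr6 comparisons may mark mouse line as well as Cxcr6. DNA carried along around Cxcr6 on chromosome 9 was not decided: 2 of the 21 lie there (9.5%, against 4.7% of genes tested, odds ratio 2.13, two-sided Fisher's exact p = 0.26). Cdcp1 lies 6 and Acpp 176 tested genes with a known position from Cxcr6. These distances were looked up after the genes were seen. Gene order covered only the 13494 of 18337 tested genes with a known position, and random sets were drawn from these. The 21 genes did cluster along chromosomes, with 13 pairs within 100 such genes of each other, against a median of 3 in 10000 random sets (one-sided permutation p = 2e-04), with groups on chromosomes 2, 3, 6, 13 and 18. This is what segments of another strain background, present in only 1 of the lines, would give, and is consistent with line rather than Cxcr6 loss as the source for part of the set; some neighbours, such as Selenbp1 and Selenbp2, are relatives that can share signal. The count of pairs describes the set and cannot decide the source for any single gene, inside or outside such groups. Cxcr6 loss itself stays open for each of the 21 genes, and DNA carried along around Cxcr6 stays open for Cdcp1 and Acpp.

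For double KO against Nemo KO, 1 of the 10 splits of the 6 arrays, the real one, gave 109 genes and the highest other split gave 0. For double KO against Cxcr6 KO, the real split (1 of 10) gave 1358 and the highest other gave 0. With 10 splits a share under 0.05 cannot be reached.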

How the results depend on the processing

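Counts of changed genes depended on the settings more than directions did, and the cause was not tested. For Nemo KO against wildtype (29) the count was 7 without a filter, 127 with a stricter filter, 11 with quantile normalization, 1319 with median centring, 11 with trend and robust variance, 0 with array weights, 0 with only the groups compared, and 607 at an unadjusted p under 0.05 and 2-fold. For double KO against Nemo KO (109) it was 61 with a stricter filter, 201 with median centring, 971 with array weights, 11 with only the groups compared, 39 at 5% and 2-fold, and 208 at an unadjusted p under 0.05 and 2-fold. For double KO against Cxcr6 KO (1358) it was 4692 with array weights, 2766 with only the groups compared, 460 at 5% and 2-fold, and 798 at an unadjusted p under 0.05 and 2-fold. For Cxcr6 KO against wildtype (47) it was 24 without a filter, 28 with median centring, 16 with array weights, 0 with only the groups compared, and 287 at an unadjusted p under 0.05 and 2-fold. The interaction (0) gave 443 at an unadjusted p under 0.05 and 2-fold. Replicate numbers did not pair the arrays (15 pairs of the same number, median r 0.06 against 0.02 for other pairs), and with the number as a block the counts were 0, 61, 1507, 24 and 0.

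With each array left out in turn the counts ran from 0 to 2380, 19 to 161, 116 to 2342, 8 to 493 and 0 to 232, in the order above. A lone wildtype array is assumed to vary like the other groups. The share of same signs ran from 47.31% to 100% for genes called in Nemo KO against wildtype, 71.21% to 91.54% for double KO against Cxcr6 KO, 46.86% to 100% for Cxcr6 KO against wildtype and 54.9% to 91.67% for double KO against Nemo KO. The share for Cxcr6 KO against wildtype was 97.78% with quantile normalization and 100% with the block, and that for double KO against Nemo KO was 79.07% without a filter.

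Lists whose tested direction turned did so only without a wildtype array, and the cause was not tested. With each array left out in turn, medians in Nemo KO against wildtype ran from -0.296 to 0.682 for lipogenesis and -1.311 to 0.276 for female-biased genes. In Cxcr6 KO against wildtype they ran from -1.148 to 0.158 for cell cycle, -0.465 to -0.042 for NF-kB targets, -0.52 to 0.072 for interferon response, -0.747 to 0.255 for antigen presentation, -0.203 to 0.734 for Nrf2 targets, -0.747 to 0.243 for endoplasmic reticulum stress and -0.022 to 0.944 for lipogenesis. The interaction medians ran from 0.043 to 0.764 for interferon response and 0.09 to 1.2 for Kupffer cell markers. Signals near the array medians limit what weakly expressed genes can show.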

Other observations

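Some circadian clock genes had group means in Cxcr6 KO away from those of the other 3 groups, a pattern not tested as such. The clock output gene Dbp had a mean log2 signal of 10.85 ± 0.85 (SD, n = 3) in Cxcr6 KO, 7.44 ± 0.45 (n = 2) in wildtype, 7.79 ± 0.50 (n = 3) in Nemo KO and 7.60 ± 1.89 (n = 3) in double KO. Arntl, which encodes the activator BMAL1, ran the other way, with a mean of 7 (SD 0.35) in Cxcr6 KO, 10.22 ± 0.40 in wildtype, 9.11 ± 0.66 in Nemo KO and 9.66 (SD 1.5) in double KO. In double KO against Cxcr6 KO, Arntl (2.65, adjusted p = 0.0438) and Clock (0.91, adjusted p = 0.0421) rose, while Hlf (-1.05, adjusted p = 0.0217), Usp2 (-2.25, adjusted p = 0.0401) and Nr1d2 (-1.83, adjusted p = 0.0473) fell. Of the 20 genes of the list, 3 rose and 5 fell over all genes, 4 rose and 10 fell adjusted over the list alone, and camera, which asks for a shared direction, did not call it (adjusted p = 0.323). In Cxcr6 KO against wildtype, Dbp (3.41, adjusted p = 0.186), Arntl (-3.22, adjusted p = 0.14) and the other clock genes did not pass. Arntl, Clock and Nr1d2 were chosen, and the genes grouped by direction, after their values were seen, and the hours of sampling are not in the sources used here. Whether the hour adds to the falls of Dbp, Rgs16 and Usp2 in double KO against Cxcr6 KO, or to its count, was not tested. Cdkn1a also stands in the clock list.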
